A study of Drosophila melanogaster with 2 samples.

How the data were processed

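Each of the 2 samples is a total small RNA library from adult ovaries, 1 control and 1 Nup358 germline knockdown, without an oxidation step. Per the labels' protocols, small RNA was cut from a gel, ligated with the TruSeq small RNA kit with an oligonucleotide that blocks 2S rRNA, size-selected and sequenced in single reads of 50 cycles. The reads reach 69 nt, which that cycle number does not explain. Per the submitters' processing notes, cutadapt, featureCounts and build dm3 were used, with no versions given. The deposited values are raw counts: each file holds 1 row per distinct read sequence with the number of reads, and no position or feature name. The counts were used as deposited.

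Reads were classified by sequence with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A miRNA read is 28 nt or shorter and holds nt 3 to 20 of one of 86 mature sequences, starting within 2 nt of the listed start. The miRNA, tRNA, U6, 2S, 5S, 5.8S and esi-2.1 sequences were written down from general knowledge of the published ones. For 55 of the 60 miRNAs with at least 100 reads, the most read form began at the listed end and was within 2 nt of the listed length. Forms with a changed base in nt 3 to 20 were not counted as miRNA, except in an added alternative. miRNAs with no read were not interpreted. The miRNA list was set before counts were seen. The list of 8 tRNAs was completed after counts had been seen, and fragments of other tRNAs remain among the unassigned reads.

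18S and 28S rRNA were assembled from the reads themselves by extending 9 conserved seeds, and reads up to 44 nt inside these stretches were called rRNA. The setting for this was changed after a first complete set of results had been seen. At first the stretches were extended over 18-mers read 20 times or more, which gave 1371 nt of 18S in 3 pieces, and abundant 28S fragments were then noticed among the unassigned reads. Of 10 settings tried, 16-mers read 5 times or more was kept because it gave 18S in 1 piece of 1996 nt and 2898 nt of 28S. The 3 looser settings that also joined 18S gave longer 28S stretches, 3643 and 3750 nt with minimums of 3 and 2 and 2976 nt with 15-mers, but added few reads: 3664025, 3678645 and 3663626 control reads against 3660920. So 28S length did not favour the setting kept over these 3. It matters for the results: recognised 18S and 28S reads went from 2563578 to 3660920 in the control and from 2825007 to 4683949 in the knockdown, and the first setting is given as an alternative. 28S is still not complete, so some rRNA fragments remain unassigned.

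The denominator was fixed beforehand as reads assigned to features other than rRNA. Since the files name no features, all reads outside recognised rRNA and outside reads joined to 2S rRNA were used in its place. Log2 ratios have a prior count of 0.5. Ratio intervals are exact conditional binomial (Clopper-Pearson), shares have exact Clopper-Pearson intervals, and CPM values have exact Poisson intervals, all at 95%. PCR copies are not independent molecules, so these cover counting error only. At 3 reads the floor was 0.168 CPM in the control and 0.308 CPM in the knockdown. Lists are described by the percentile of their median among 10000 random lists matched on mean level, a description of these libraries. Random members were drawn separately, so the percentiles make no allowance for miRNAs of a cluster or complex that change together. For lists of more than 8 members a miRNA drawn more than once in a random list was kept once, so those random lists could be shorter.

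The piRNA range is unassigned reads of 23-29 nt. Overlaps were measured without a genome: 15-nt read starts on opposite strands were paired at 5′-5′ overlaps of 8 to 20 nt where the joint sequence lay in a 22-nt window of some read. Shorter overlaps, which had been planned, cannot be measured this way. Each library was thinned to 3000000 reads, 3 times. On simulated loci, the excess at 10 nt was -0.786 points with no pairs placed, 18.9 with 30% of reads placed as pairs and 39.7 with 60%. In simulated counts for 5835 piRNA-range sequences compared between the libraries, 100% of sequences changed 2-fold or 4-fold were called in the right direction and 4.51% of unchanged ones were called. These counts were drawn with counting error alone, as the intervals assume. The 4.51% is therefore not the rate of false calls between real libraries.

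Named RNAs were chosen by a rule set before the data were examined: list members with at least 100 reads, the 10 highest and 10 lowest log2 ratios among those with at least 200 reads whose interval leaves out 0, and the 10 most read. It was applied to the listed miRNAs, tRNAs and other RNAs. The candidate hairpin strands were chosen after the data were seen. Reads of the luciferase hairpin that the control expresses were not sought. Any such reads stay among the control's unassigned reads, also in the alternative without tRNA and hairpin reads. Alternatives were other denominators, prior counts, read minimums, counting each distinct sequence once, and those added later. Transposon families, piRNA clusters, genic piRNA loci and the other endo-siRNA loci were planned but not analysed here, since no genome or transposon sequence was used.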

Results

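Total small RNA from adult Drosophila melanogaster ovaries was sequenced in 2 libraries. One came from control ovaries that express a luciferase hairpin under a maternal germline driver (mat>Luc). The other came from ovaries with a germline knockdown (GLKD) of Nup358, a large nucleoporin of the cytoplasmic face of the nuclear pore. The title of the series names transposon silencing and piRNA biogenesis as the question. The control library held 22380480 reads of 3127830 distinct sequences and the knockdown library 15174492 reads of 1936947 distinct sequences, all between 18 and 69 nt long. Outside recognised ribosomal RNA, 17905136 control reads and 9739766 knockdown reads remained, and these totals are the denominators of the log2 ratios and of CPM (counts scaled to a total of 1000000). With 1 library per group no test between the conditions was possible and no difference has a replicate check. Intervals in brackets are exact 95% intervals and cover counting error only. The choice of denominator shifts every log2 ratio alike, by 0.42 upward when miRNA reads are the denominator, 0.32 downward when all reads are, and 0.74 downward under a median-of-ratios scaling over 13710 sequences. Those sequences had at least 50 reads in each library. Fragments of rRNA and tRNA, which were higher in the knockdown, were not left out of them.

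The targeted gene was looked at first. No genome position came with the reads, so reads of Nup358 itself were not analysed here, and the nearest measurement is a 22-nt sequence seen almost only in the knockdown library. TGAATTGTTATGAACATCCGGG was the most read sequence of the knockdown library, with 321232 reads against 223 in the control. With its length variants it had 447180 against 325 reads, a log2 ratio of 11.30 (11.15 to 11.47). Those of them that were 21 or 22 nt long, 406971 reads, made up 13.9% of all knockdown reads of these lengths. A complementary 22-nt sequence, CGGATGTTCATAACAATTCATA, had 1186 reads in the knockdown and 1 in the control, and the pair overlaps by 20 nt as the guide and passenger of a short hairpin do. The knockdown held 271 guide reads per passenger read. Both sequences were chosen after their counts were seen and were not placed on Nup358 here.

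The makeup of the small RNA differed widely between the libraries. Ribosomal RNA fragments, excluding reads joined to 2S rRNA, took 35.21% of the knockdown reads (35.18 to 35.23) and 19.60% of the control reads (19.58 to 19.61). Fragments of 8 abundant tRNAs took 12.63% (12.61 to 12.65) against 3.605% (3.598 to 3.613), which is 4.37-fold more per non-rRNA read in the knockdown (log2 2.13, 2.12 to 2.13). Matched miRNAs took 9.79% (9.77 to 9.80) against 16.28% (16.27 to 16.30), with a log2 ratio of -0.416 (-0.419 to -0.413). Of the 3643711 control miRNA reads, miR-312 held 1015155 and miR-318 held 432968. Of the 1485481 knockdown miRNA reads they held 68960 and 37348. Both therefore weigh heavily in this total and in every value given per miRNA read. Unassigned reads of 23-29 nt, the piRNA range, took 21.90% (21.88 to 21.92) against 42.89% (42.87 to 42.91). U6 snRNA had 2637 and 3515 reads, a log2 ratio of 0.46 (0.39 to 0.54) that changes sign under the median-of-ratios scaling.

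Among the tRNAs, tRNA-Gly fragments stood out, with 63822 CPM in the knockdown against 4042 in the control, a 15.8-fold difference (log2 3.98, 3.97 to 3.99). tRNA-iMet, the initiator tRNA, followed at log2 2.67, then tRNA-Ala at 2.49, tRNA-Lys-CTT at 2.25 and tRNA-Lys-TTT at 2.08. tRNA-Glu was the most read tRNA in the control and was 1.85-fold higher in the knockdown (log2 0.89, 0.88 to 0.89). Over the 8 tRNAs, fragments that begin at the 5′ end were 5.19-fold higher in the knockdown (log2 2.38). The remaining fragments, which neither begin there nor end in the 3′ CCA, were 4.89-fold higher (log2 2.29). Fragments that end in the 3′ CCA were higher in the knockdown for 5 of the 7 tRNAs with enough such reads, from log2 0.32 for tRNA-Asp to 3.31 for tRNA-His, and lower for tRNA-Glu (log2 -1.33) and tRNA-Gly (log2 -1.38). Their sum was lower in the knockdown (log2 -0.53, -0.54 to -0.51), but tRNA-Glu held 109409 of the 144162 control reads, and without it the log2 ratio was 0.70 (0.67 to 0.72). Both this value and that of tRNA-Asp change sign under median of ratios, to -0.043 and -0.42, and per all reads tRNA-Asp does not differ from 0, so that 4 of the 7 are higher under these 2 scalings.

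The length profile showed the piRNA-range peak lower in the knockdown. Unassigned reads of 23-29 nt made up 34.1% of the non-rRNA reads of the knockdown and 53.6% of those of the control, a 1.57-fold lower level (log2 -0.652, -0.654 to -0.650). The log2 ratio was lowest at 26 nt (-0.756, -0.760 to -0.752), with an overlapping interval at 24 nt (-0.751, -0.756 to -0.746). At 29 nt it was -0.19 (-0.20 to -0.18), a value that changes sign when miRNA reads are the denominator. Over all reads, 54.94% of the control (54.92 to 54.96) and 43.30% of the knockdown (43.27 to 43.32) were 23-29 nt long, and 23.01% (22.99 to 23.02) against 26.42% (26.39 to 26.44) were 18-22 nt long. The lower piRNA-range level depends on the denominator and on how much rRNA is recognised. The log2 ratio was -0.24 with only the denominator changed to miRNA reads. It was -0.55 with only the first, less complete rRNA assembly, and 0.029 with both changes together.

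**Figure D1:**
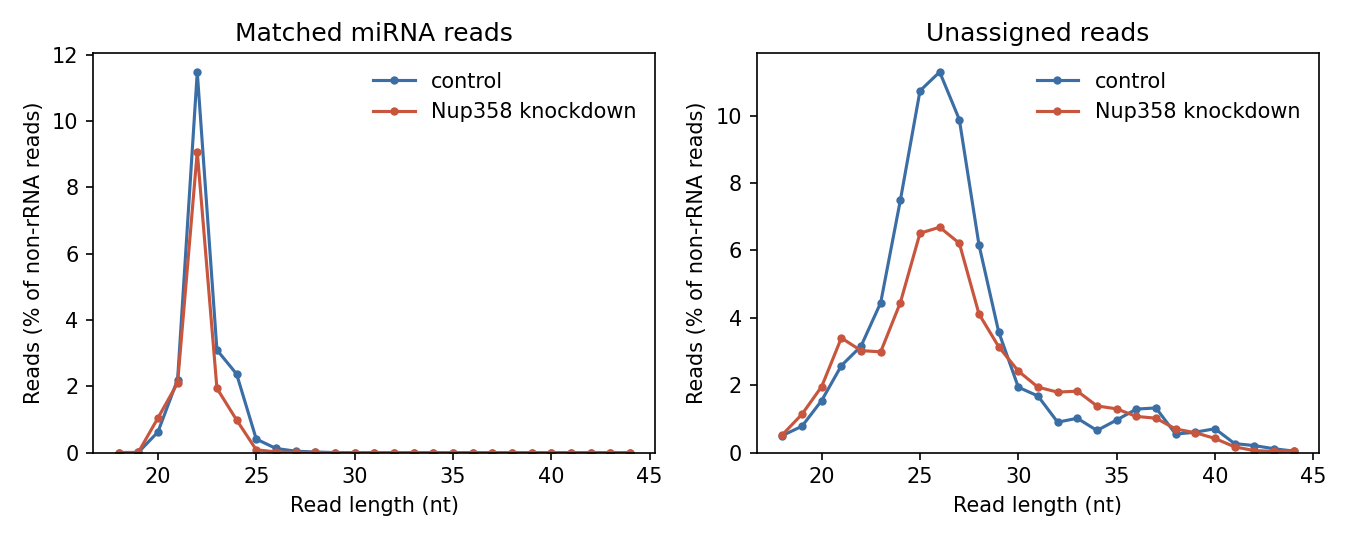
Reads of each length as a percentage of non-rRNA reads (y axis) against read length in nt (x axis), for matched miRNAs (left) and unassigned reads (right), with 1 library per line. The unassigned peak at 25-27 nt is lower in the Nup358 knockdown library than in the control library, with a log2 ratio of -0.76 at 26 nt.

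The features that mark piRNAs were also weaker in the knockdown library. Among unassigned 23-29 nt reads, 63.1% of the control (63.1 to 63.2) and 53.0% of the knockdown (52.9 to 53.0) began with U, the usual first base of primary piRNAs. Counted once per distinct sequence the shares were 55.5% in both. Among reads that did not begin with U, an A at position 10, the mark of ping-pong partners, was found in 35.2% of the control (35.2 to 35.3) and 24.8% of the knockdown (24.7 to 24.8), and in 32.9% and 30.2% of distinct sequences. The difference is not specific to these reads: among first-U reads the share was 30.6% in the control and 25.9% in the knockdown. In the ping-pong cycle, Aub and Ago3 cut opposite strands so that partner piRNAs overlap by 10 nt at their 5′ ends. After thinning both libraries to 3000000 piRNA-range reads, 31.5% of control reads and 17.7% of knockdown reads had an opposite-strand partner at 10 nt, against means of 17.5% and 11.1% over the 12 other overlaps from 8 to 20 nt. The excess at 10 nt was thus 13.9 percentage points in the control and 6.54 in the knockdown, with z-scores of 11.0 and 7.18. The order of the z-scores depends on the measure: on products of read counts they were 59.8 in the control and 128 in the knockdown. Pairs of reads at 10 nt exceeded the mean of other overlaps 2.23 times in the control and 1.87 times in the knockdown. Counted once per distinct sequence, these ratios were 1.22 and 1.20.

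**Figure D2:**
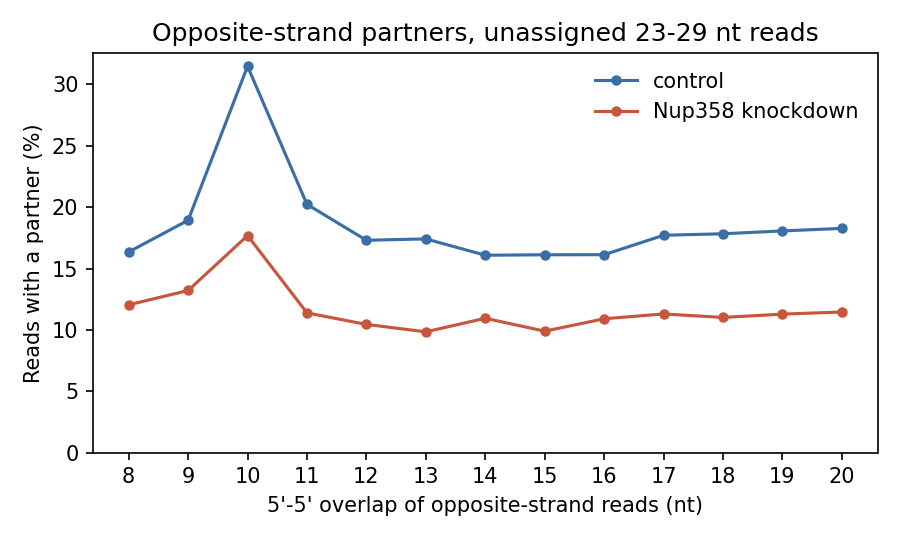
Percentage of unassigned 23-29 nt reads with an opposite-strand partner (y axis) against the 5′-5′ overlap in nt (x axis), 1 line per library, each thinned to 3000000 reads. Both libraries peak at 10 nt, at 31.5% in the control and 17.7% in the knockdown.

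Reads of sequences with a 10-nt partner were 2.64-fold lower in the knockdown (log2 -1.400, -1.404 to -1.397). Those with opposite-strand reads at other overlaps only were 1.66-fold lower (log2 -0.73, -0.74 to -0.73). Reads with no opposite-strand read had a log2 ratio of -0.080 (-0.083 to -0.078), which turns positive when miRNA reads are the denominator, and this class would also hold rRNA and tRNA fragments that were not recognised. Of 5835 single sequences with at least 200 reads, 4410 were lower and 917 higher in the knockdown beyond counting error, with a median log2 ratio of -1.51. The first-U sequences had a median of -1.70 and the others of -0.96. Summed, these sequences had 3605572 control and 1183102 knockdown reads, a log2 ratio of -0.73, so the median weighs the less read sequences more. Since the control is deeper, choosing by summed reads favours sequences lower in the knockdown: the same number of sequences ranked by mean CPM had a median of -1.26, with 4065 lower and 1186 higher. Over the scalings the median ranged from -1.10 per miRNA read to -2.25 under median of ratios for the first choice, and was -0.84 per miRNA read for the ranking by mean CPM. Of the 5 most read sequences 3 were lower, among them TACTTGTTCCCCGGATAGTTTAGTTAC at log2 -1.07, and 2 were higher, GCGGAGGTTGCGGTGCTGTACACTG at 0.37 and GGCTCGTTGGTCTAGGGGTATGATTTC at 0.78. None of the single sequences was placed on a genome. Fragments of unlisted tRNAs or of rRNA may be among them, also among the higher ones.

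miRNAs moved in both directions. Of 60 miRNAs with at least 100 reads, 28 were higher and 27 lower in the knockdown beyond counting error, with a median log2 ratio of -0.01 and a range from -4.63 to 3.63. This split depends on the scaling: it was 37 higher and 20 lower per miRNA read, and 19 higher and 37 lower under median of ratios. The miR-309 cluster, which is known from early embryos, was the lowest list. Its 4 members with enough reads were all lower, with a median of -3.67, at percentile 0.05 of 10000 random lists matched on mean level. The random lists drew miRNAs separately, so this percentile makes no allowance for members of a cluster changing together. miR-286 had 4163 control and 91 knockdown reads (log2 -4.63, -4.95 to -4.34), miR-5 had 714 and 22 (log2 -4.11), miR-3 had 198 and 11 (log2 -3.23), and miR-6 had 807 and 63 (log2 -2.79). In the late follicle list, miR-318 (log2 -2.66, -2.67 to -2.64) and miR-994 (log2 -3.21, -3.26 to -3.17) were lower, while miR-989 was higher (log2 1.40, 1.38 to 1.42). The list's median was -2.66 and its mean -1.49, at percentile 5.48.

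**Figure D3:**
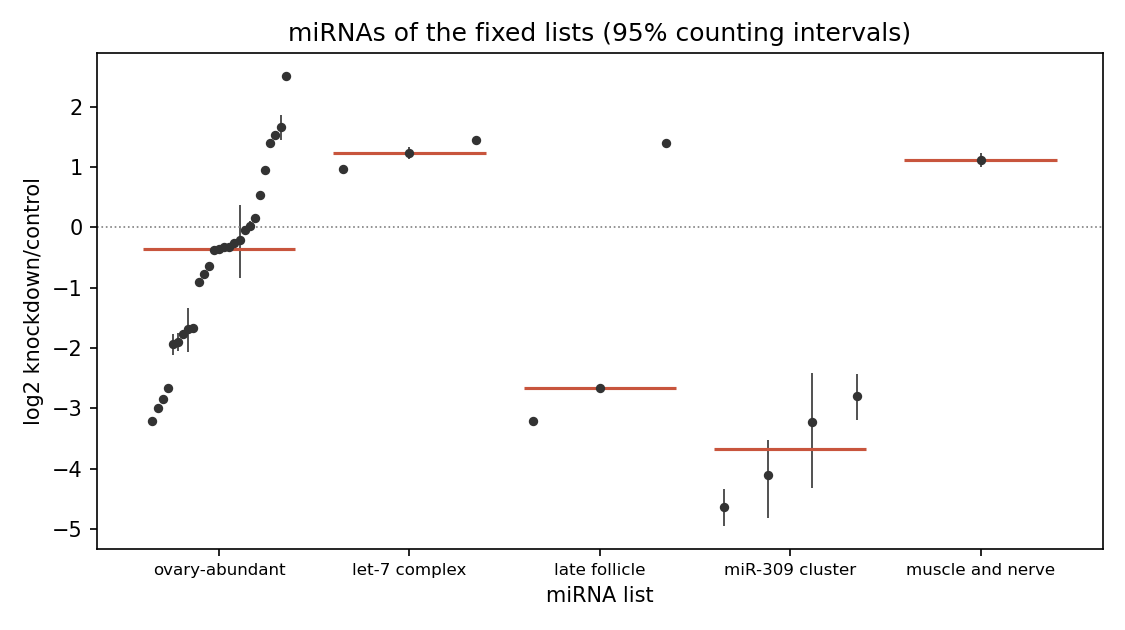
log2 knockdown/control ratio (y axis) of each miRNA with at least 100 reads, by the list fixed beforehand (x axis), with 95% counting intervals as bars and the list median as a red line. The 4 miR-309 cluster members lie between -4.63 and -2.79, and the 3 let-7 complex members between 0.97 and 1.46.

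The ovary-abundant list held 27 miRNAs with enough reads, of which 7 were higher and 17 lower. Its median was -0.36, at percentile 7.86, and it turned to 0.060 when miRNA reads were the denominator. miR-312, the most read miRNA of the control, had 56696 CPM in the control and 7080 in the knockdown (log2 -3.001, -3.013 to -2.990), and of the other members of its cluster, miR-311 had a log2 ratio of -2.84, miR-313 of -1.69 and miR-310 of 0.026 (-0.052 to 0.104). bantam, a growth-promoting miRNA, was at -1.67 (-1.69 to -1.66), miR-281 at -1.94, and miR-1010, outside the lists, at -2.04. miR-184, the second most read miRNA of the control, was at -0.32 (-0.33 to -0.32), and its sign changes with miRNA reads as the denominator and without tRNA and hairpin reads. Other ovary-abundant miRNAs were higher. miR-14, which limits cell death and fat storage, had 23639 CPM in the knockdown against 4154 in the control (log2 2.509, 2.497 to 2.521), miR-263a had a log2 ratio of 0.95 and miR-276a of 1.53. The miR-276a value leaves out a form with 1 changed base that only the control held in number, and with it the log2 ratio was 1.08 (1.07 to 1.09). Outside the lists, miR-34 was at 2.24 and miR-278 at 1.91.

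The let-7 complex, whose miRNAs are induced by the steroid hormone ecdysone, was higher in all 3 members, with miR-100 at log2 1.46, miR-125 at 1.24 and let-7 at 0.97, or 1.21 with a changed form seen in the knockdown. Its median of 1.24 was at percentile 92.3 of the random lists. miR-1, a muscle miRNA and the only member of the muscle and nerve list with enough reads, was higher as well (log2 1.11, 1.00 to 1.23). The endogenous siRNA esi-2.1 had 1070 knockdown and 998 control reads, a log2 ratio of 0.98 (0.85 to 1.10).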

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

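All tests of explanations here were chosen after the result was seen. A signal outside the comparisons, higher in the knockdown than in the control, was found in 4 places. Duplexes of 21-nt reads seen in only the knockdown library reached 1044 CPM in 368 of 1800 such sequences. In the control they reached 99.9 CPM in 160 of 2994. By overlap, the knockdown's partner share was 11.2% at 17 nt, 15.0% at 18, 14.3% at 19, 12.2% at 20 and 10.1% at 21. No single overlap stood out, and the origin of these duplexes was not tested. Reads joined to 2S rRNA were 0.608% of all knockdown reads and 0.401% of control reads. The remaining places are single-base forms of let-7 and miR-994.

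Positions are counted from 1 at the 5′ end of the miRNA. The form miR-994 T10G made up 23.2% of knockdown reads (21.6 to 24.8) and 0 of 37740 control reads (upper limit 0.00977%). The form let-7 T16G made up 15.6% (14.5 to 16.7) against 0 (upper limit 0.104%). In the opposite direction, miR-276a T9G made up 26.9% of control reads and 0.0276% of knockdown reads. These came from a search of 2640 changes in 44 miRNAs, of which 6 passed 5%. The other 3 were the base at which miR-2a and miR-2b differ from each other, seen from either side, and miR-986 C11T, at 21.2% in the control and 33.8% in the knockdown. For the let-7, miR-994 and miR-276a forms, sequencing error at these positions is argued against, since the same change reached at most 0.102% in any other miRNA of the same library that was compared. For these 3 a related gene in a shared genome is argued against too, since the upper limit in the other library was at most 0.104%. Their length profiles and those of the listed reads differed by 0.80 points for miR-276a, 3.40 for miR-994 and 17.01 for let-7. An allele of the miRNA gene carried by the flies of one library stays open, but similar lengths do not single it out. With these forms included, the log2 ratio went from 1.53 to 1.08 for miR-276a, from -3.21 to -2.99 for miR-994 and from 0.97 to 1.21 for let-7. With 1 library per group, a difference between fly stocks and any effect of the knockdown stay confounded.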

How the results depend on the processing

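The alternatives without tRNA and hairpin reads, with rRNA over 18-mers (the first setting run), with the first 19 nt matched, without thinning, with products of read counts, with single-base forms included and with piRNA-range sequences ranked by mean CPM were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Transposon reads of 23-29 nt only, single or split assignments and medians over copies were not run. Since 1 library per group gives intervals from counting alone, most shifts exceed them. Of 44 miRNAs and tRNAs under the naming rule, 7 whose interval left out 0 changed sign under at least 1 of the 5 scalings tried. A further 3 (miR-310, miR-2b and miR-996) had 0 within their interval. They are not among the 7, though their values also changed sign under at least 1 scaling. Per miRNA read miR-8 was at 0.15, miR-11 at 0.096, miR-184 at 0.095, miR-92b at 0.060 and miR-2a at 0.040, and without tRNA and hairpin reads miR-8 was at 0.072, miR-11 at 0.015 and miR-184 at 0.014. miR-13b, at 0.15 in the main scaling, was at -0.17 per all reads, -0.59 under median of ratios and -0.015 with rRNA over 18-mers, and miR-279, at 0.54, was at -0.20 under median of ratios. Including single-base forms moved miR-276a to 1.08 and miR-994 to -2.99 and no list median. Ranking piRNA-range sequences by mean CPM moved their median from -1.51 to -1.26. A prior count of 5 and an exact match of the first 19 nt left every value they were run on within its interval or 1.5 times its count.

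Log2 ratios are given in the order piRNA range, all miRNAs, tRNAs, esi-2.1, hairpin guide, then the medians of the ovary-abundant, let-7, late follicle, miR-309 and muscle lists. Per miRNA read, without all miRNAs, they were -0.24, 2.54, 1.39, 11.72, 0.060, 1.66, -2.24, -3.25 and 1.53, so the ovary-abundant median changed sign. Per all reads they were -0.97, -0.73, 1.81, 0.66, 10.98, -0.67, 0.92, -2.97 and 0.79, leaving out the miR-309 list, which stayed within its interval. Under median of ratios they were -1.39, -1.16, 1.39, 0.24, 10.56, -1.10, 0.50, -3.40, -4.41 and 0.37. Without tRNA and hairpin reads, leaving out tRNAs and the miR-309 list, they were -0.32, -0.081, 1.31, 11.64, -0.021, 1.57, -2.32 and 1.45. With rRNA over 18-mers, leaving out the miR-309 list, they were -0.55, -0.58, 1.96, 0.81, 11.14, -0.52, 1.07, -2.82 and 0.95. These shifts follow from the denominators alone, except that the piRNA range also holds more reads under the 18-mer setting. With rRNA over 18-mers and miRNA reads as the denominator together, the piRNA-range log2 ratio changed sign to 0.029. A minimum of 1 read moved the muscle and nerve list to 1.62, and a minimum of 1000 reads moved the miR-309 list to -4.63, where it rests on miR-286 alone.

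The 18-mer setting gave rRNA shares of 15.1% in the control and 23.6% in the knockdown, here including reads joined to 2S rRNA. The matching shares in the main setting were 20.0% and 35.8%. The 18-mer setting also gave first-U shares of 61.3% and 44.4%, excesses at 10 nt of 13.2 and 4.76 points, and a knockdown pair ratio of 1.90. The gap between the libraries in first U and in the excess was thus wider before more rRNA was recognised. As shares of reads other than rRNA, miRNAs made up 20.4% and 15.3%. Counting each distinct sequence once gave first-U shares of 55.5% in the control and 55.5% in the knockdown, and pair ratios of 1.22 and 1.20, so the differences in these measures lie mostly in abundant sequences. Without thinning the excesses were 13.2 and 6.46 points, but the ratio at 10 nt to other overlaps was then higher in the knockdown, at 1.55 against 1.49 for reads with a partner and 1.19 against 1.12 for distinct pairs. At equal read number these ratios were 1.59 against 1.80 and 1.20 against 1.22, so the unthinned order follows from unequal depth. Products of read counts gave pair ratios of 20.9995 and 16.6; the cause was not tested. Depth limits miR-309 itself, with 21 control and 0 knockdown reads, and the muscle and nerve list, where 1 of 3 members had enough reads.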

Other observations

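All tests of explanations here were chosen after the result was seen. miRNA ends differed between the libraries. Reads with 2 or more A beyond the listed 3′ end were counted for 35 miRNAs with at least 500 full-length reads in each library. Their share was larger in the control for 12 and in the knockdown for 1 (miR-263a), and 22 had overlapping intervals. Whether these A are encoded in the genome was not checked. miR-312 had 34.97% with such tails in the control and 21.8% in the knockdown, and miR-92a 42.9% and 13.9%. Other tails beyond the listed end had medians of 0.433% in the control and 0.548% in the knockdown. The difference has no replicate check.

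Equal numbers of piRNA-range reads held more distinct sequences in the knockdown, 1002266 against 884155 in 3000000 reads.

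The lower miR-309 cluster, miR-318 and miR-994 were set against explanations. Scaling is argued against: the highest of the list median, miR-318 and miR-994 over all scalings was -2.24. A lower recovery of miRNAs of that length is argued against by the median of 0.089 over the 40 other miRNAs of 22 and 23 nt. One biological candidate explanation, fewer late-stage egg chambers, was not decided. Of the 3 late follicle miRNAs, miR-318 and miR-994 were lower and miR-989 was higher, at 1.40. The miR-989 value shows only that the 3 were not all lowered, and it had been seen before the explanation was worded. A change in stage makeup combined with a separate increase of miR-989 stays open and was not tested.

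The lower ping-pong share was weighed in the same way. Depth is argued against, since in equal numbers of reads the excess at 10 nt was still at least 7.32 points higher in the control. Dilution by unrecognised rRNA or tRNA fragments as the whole cause was set against the ratio of pairs at 10 nt to other overlaps. With 50% of the control's reads replaced by recognised fragments, this ratio rose from 2.23 to 2.34. The smallest difference from the knockdown, 0.36, was thus the one without added fragments. Recognised 18S and 28S reads had 0.12 antisense reads per 100, so adding them could hardly lower the ratio. Dilution by such fragments would not account for the knockdown's lower ratio, but fragments read from both strands were not tried. This holds for the pair ratio only. In the same mixtures the excess at 10 nt fell from 15.0 points without added fragments to 7.62 at 40% and 7.73 at 50%. The knockdown's excess was 6.54. As part of the cause dilution stays open, and at such shares of fragments it could make up much of the gap in the excess. Recognising more rRNA narrowed this gap by 1.03 points, from 8.44 to 7.40, and the amount of fragments still unrecognised is not known. A larger share of somatic piRNAs, which lack ping-pong, cannot be told apart from a loss of germline piRNAs, because reads with no opposite-strand read had a log2 ratio of -0.080 that ranged from -0.82 to 0.34 with the scaling, and no somatic locus was identified. An effect of the knockdown on piRNA production stays among the open explanations.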
